A study of Rattus norvegicus with 8 samples.

How the data were processed

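RNA was measured by sequencing in periodontal ligament (PDL), the connective tissue that anchors the tooth root to bone, taken from the cervical region of rat (Rattus norvegicus) teeth by laser micro-dissection. Per the labels, the libraries were made from total RNA with a low-input kit (SMARTer Ultra Low), and 4 animals were sampled at each of 2 ages, postnatal day 18 (P18) and postnatal day 28 (P28). Each of the 8 libraries was taken as 1 animal.

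The authors deposited a table of raw counts per gene symbol, with 17337 genes. Per the submitters' processing notes, STAR 2.5.3a, HTSeq 0.9.1 and edgeR 3.16.5 were used with the genome build rn6; the role of each tool, the annotation and the strand setting of the counting are not given in the sources used here. The authors also deposited a normalized signal table of 12742 genes, in which each value is the count multiplied by 1 constant per library. Within a library, the value per count was constant to a relative spread of 1.3e-08 over the 12719 entries that matched the count table by name; 23 entries carry dates in place of gene names. The totals of the 8 columns in that table ran from 976276 to 1194090. Each table also holds 40 columns of other samples, which were not used in any step.

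Genes were tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, 2-sided), with TMM scaling, age as the only term, and the expression filter of edgeR by age (minimum count 10), which left 10472 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM are counts scaled to library size with TMM factors, given as mean ± SD over the 4 libraries of an age. Log2 fold changes are P28 over P18, given ± SE, where the SE is the size of the fold change divided by the root of its F statistic. Log2 CPM used a prior count of 2. A total of 36 gene lists were tested with camera of limma 3.58.1 (competitive, 2-sided) on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 36 lists; the minimum was 3 tested members. The count of called members was also taken with p adjusted over the list alone. Single values were compared with exact permutation tests (2-sided), whose smallest possible p with 4 against 4 libraries is 0.0286.

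The 36 lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined; a list of imprinted genes and a list of melanocyte genes, used only in the closing section, were written later. The rule named (a) the 12 genes with the largest fold change in each direction among those with an adjusted p under 0.05, a mean log2 CPM of at least 3, no overlap between the libraries of the ages and a symbol that is not a placeholder; (b) Lmna, Lmnb1, Notch1, Notch2, Notch3, Notch4, Jag1, Jag2, Dll1, Dll4, Hes1, Hey1, Heyl, Nrarp, Scx, Tnmd, Mkx, Postn, Col1a1 and Col3a1, whatever their result; and (c) up to 4 members with the lowest p from each list described. The 16 lists described in the results under (c) were chosen after the results of all 36 were seen; the remaining lists are given in the closing section. Jag2 and Mkx were not analysed here, and some genes named under (c) are not reported here. List members under another symbol were matched through a RefSeq gene table (assembly GRCr8), in which 14821 of the symbols in the count table matched a symbol and 2125 a synonym. That table was used for names and for neighbouring genes only. Coordinates on rn6 were not used here, so none are given.

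The fit was tested on simulated counts drawn from the means, library sizes and dispersions of the real libraries (10202 genes tested, 5 draws). Of 100 genes per draw changed 2-fold, 10.2% were called, and of 100 changed 4-fold, 54.8%; of the calls, 4.69% were of unchanged genes. In this simulation most 2-fold changes were not called with 4 libraries against 4. The changed genes, and the shifted list that follows, were drawn only from genes above a minimum mean CPM. The shares called therefore do not cover genes of lower expression. A simulated list of 30 genes shifted 2-fold was called in 5 of 5 draws, and 0 of 175 unshifted lists were called. The simulated genes were drawn independently of each other. These list results therefore do not cover lists whose members move together, as real lists can (estimated correlation up to 0.716, in the neutrophil list). In the real data the biological coefficient of variation was 0.704, and the median SE of a log2 fold change was 0.49.

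Total counts per library ran from 5252693 to 26645656. A count of 0 allows up to 3 counts, which is 0.108 CPM in the deepest library and 0.624 CPM in the shallowest; such limits and intervals (95%) cover counting error only; no molecular identifiers are named in the labels, and reads copied by PCR are not independent molecules. The alternatives were DESeq2 size factors, upper-quartile scaling, the Wald test of DESeq2 1.42.0, limma with voom and sample quality weights, no filter beyond 1 count in total, a filter of 10 counts in 4 libraries, glmTreat against a fold of 1.5, limma-trend on the log2 of the authors' normalized values (pseudocount 1, a value of at least 1 in 4 libraries), leaving out each library in turn, adding the subject number to the model, and, for lists, an estimated correlation and the rotation test fry for a shared direction. The mixed test of fry, for change in either direction, was added after the data were seen.

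Some genes share reads with near copies or overlap a neighbour, and their counts are uncertain: metallothionein genes, the globin genes Hbb and Hbb-b1, ribosomal protein genes (many processed pseudogenes), and Scx, Col1a1 and Dll1, which overlap Bop1, Sgca and Fam120b in the RefSeq table. Klf4, Fmod, Gpc3, Syne3, Aph1a, Amelx, Heyl, Dll4, Bmp1, Ahsp and Rpl13 also overlap a neighbour there. The symbols of those neighbours are not in the count table, and whether the counting used them is not known.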

Results

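The series compared the PDL before and after the teeth come into occlusal contact, which falls between P18 and P28, and its title names Notch signalling and Lamin A. Cervical PDL was captured from 4 animals at P18 and 4 at P28. Total counts were 10863769, 26645656, 21673970 and 18719931 in P18 replicates 1 to 4, and 17803006, 9083624, 13829437 and 5252693 in P28 replicates 1 to 4. Between 10063 genes (P28 replicate 4) and 11661 genes (P28 replicate 2) had at least 1 count. Col1a1, the main fibrillar collagen of ligament, was the most abundant gene in every library except P28 replicate 3, where Col3a1 took its place. The top gene held 4.03% to 8.11% of the counts of a library. P28 replicate 4 stood apart. Its correlations across genes (log2 CPM; genes are not independent replicates) with the other P28 libraries were 0.750 to 0.766, against 0.813 to 0.827 among these, and it lay at 163 on a first principal component (26.9% of the variance) on which the other 7 libraries lay between -40.9 and 3.60.

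At P28, 54 genes were higher and 44 lower than at P18 among 10472 tested (edgeR quasi-likelihood test, adjusted p under 0.05). Genes named by the fixed rule (mean log2 CPM of at least 3, no overlap between ages, 12 in each direction) included metallothioneins, an osteoclast phosphatase and osteocalcin among the higher and enamel matrix genes and the ligament marker Tnmd among the lower. In all 98 called genes the libraries of the ages did not overlap. That was so for 1094 tested genes (10.4%), where chance gives 2.86%, and 1523 genes had an unadjusted p under 0.05. The counts depended on single libraries. Without P28 replicate 4, 110 genes were higher and 105 lower, and 88 of the 98 calls were kept. Without P18 replicate 2, 4 were higher and 5 lower. Left out in turn, P18 replicates 1, 3 and 4 and P28 replicates 1, 2 and 3 gave 56, 23, 24, 16, 136 and 31 calls in total. The DESeq2 Wald test called 404 higher and 326 lower, all 98 among them.

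Of the genes named by that rule, the largest rise was that of Mt3, a zinc- and copper-binding metallothionein, from 7.69 ± 3.98 to 467 ± 440 CPM (SD, n = 4 per age), a log2 fold change of 5.92 ± 0.78 (SE). Another metallothionein gene, Mt2A, rose from 2.24 ± 1.22 to 46.6 ± 34.8 CPM. Igfbp6, which binds insulin-like growth factors, rose from 1.51 ± 1.22 to 80.9 ± 47.7 CPM, and Mlana, best known from melanosomes, from 2.24 ± 1.13 to 79.6 ± 39.2 CPM. Leaving out 1 library, the log2 fold change of Mt3 was 5.16 to 6.26 and that of Igfbp6 5.33 to 6.29. Which of the pair rose most is thus not settled. Klf4, a zinc-finger transcription factor, rose from 16.5 ± 5.65 to 107 ± 10.2 CPM, a log2 fold change of 2.70 ± 0.31 (edgeR adjusted p = 0.00446). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 15.4 ± 7.89 to 78.2 ± 9.22 CPM, and the galectin gene Lgals3 from 50.3 ± 18.3 to 266 ± 121 CPM. Fmod, a small proteoglycan that binds collagen fibrils, rose from 44.1 ± 40.4 to 345 ± 62.2 CPM, and Bglap, which encodes osteocalcin, from 373 ± 134 to 1722 ± 820 CPM. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, Ifi27l2b and Fxyd2 complete the 12 higher genes of the rule, at log2 fold changes of 3.67 ± 0.77, 2.93 ± 0.49 and 2.77 ± 0.53. Mt3, Mlana and Klf4 were called in all 8 fits that left out 1 library. Of the 12, the number still called was 8, 3, 7 and 7 without P18 replicates 1 to 4 and 4, 12, 5 and 12 without P28 replicates 1 to 4 (adjusted p up to 0.173, for Acp5). With voom and quality weights, the calls of Mt3 (adjusted p = 0.0548) and Acp5 (adjusted p = 0.0711) ended.

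Among the genes that fell, Tnmd, a transmembrane marker of tendon and ligament cells, went from 560 ± 119 to 104 ± 36.9 CPM, a log2 fold change of -2.43 ± 0.29 (edgeR adjusted p = 0.00608). Tmtc4, a protein of the endoplasmic reticulum, went from 109 ± 24.5 to 5.90 ± 3.24 CPM (log2 fold change -4.24 ± 0.48), and Gpc3, a cell-surface heparan sulfate proteoglycan, from 113 ± 55.0 to 10.7 ± 4.54 CPM (-3.39 ± 0.45). Mest, an imprinted gene, went from 93.8 ± 16.6 to 14.3 ± 6.90 CPM, and the lipoxygenase gene Alox15 from 1190 ± 748 to 107 ± 76.3 CPM. The enamel matrix gene Ambn fell from 800 ± 1060 to 2.39 ± 1.63 CPM. Amtn, another gene of enamel-forming cells, had 3576 counts at P18 and 2 at P28, a ratio of 954 after scaling to library size, with a 95% counting interval of 264 to 7877. That interval leaves out the spread between animals: P18 replicates 1 to 4 lay at 144, 29.8, 48.8 and 0.815 CPM. Mcm10, a DNA replication factor, the interferon-induced gene Rsad2, Spib, Fam126a and March7 complete the 12 lower genes of the rule, at log2 fold changes of -5.45 ± 1.08, -3.77 ± 0.76, -4.49 ± 0.92, -4.48 ± 0.81 and -2.84 ± 0.56. Tnmd, Tmtc4 and Gpc3 were called in all 8 fits that left out 1 library, and Spib in none. The number of the 12 still called was 8, 4, 6 and 7 without P18 replicates 1 to 4 and 4, 9, 5 and 10 without P28 replicates 1 to 4 (adjusted p up to 0.144, for Mcm10). With voom and quality weights, the calls of Ambn (adjusted p = 0.557), Amtn (0.266), Mcm10 (0.167), Spib (0.158) and Fam126a (0.0575) ended.

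**Figure D1:**
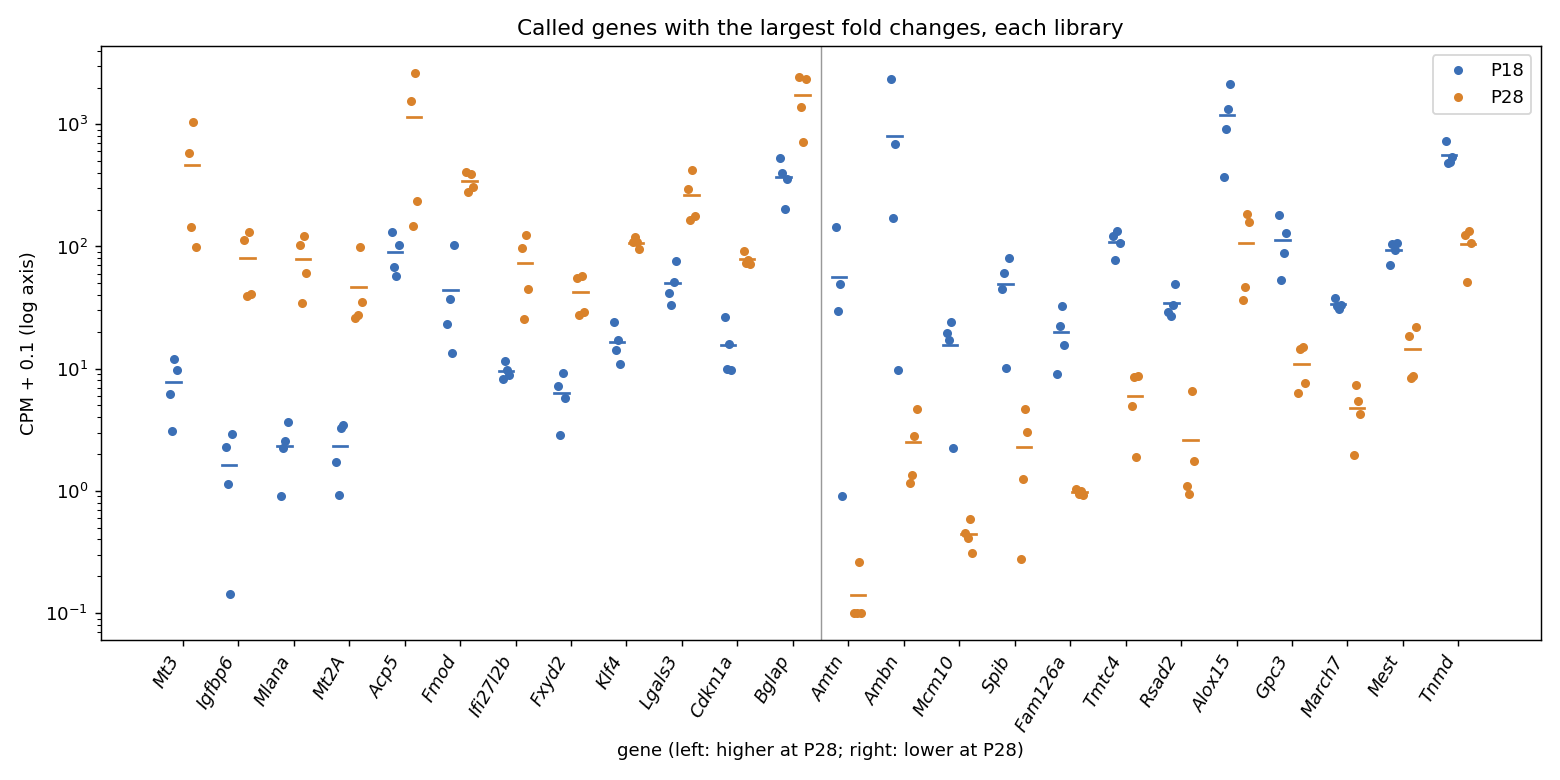
CPM + 0.1 on a log axis for the 12 genes in each direction named by the fixed rule; points are libraries (4 per age) and short bars are means. For each gene the libraries of the ages do not overlap; Klf4 and Fmod lie close together at P28, while Ambn spans 9.72 to 2329 CPM at P18.

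The gene for lamin A, Lmna, was higher in all 4 P28 libraries than in any P18 library but did not pass the test over all genes. Its level was 1190 ± 80.6 CPM at P18 and 1787 ± 354 CPM at P28, a log2 fold change of 0.59 ± 0.18 (edgeR adjusted p = 0.152; exact permutation p = 0.0286, the smallest that 4 against 4 allow). It passed without P28 replicate 4 (0.70, adjusted p = 0.0481) and in the DESeq2 Wald test (0.59, adjusted p = 0.0198). Lmnb1, a B-type lamin, lay at 66.6 ± 31.8 CPM at P18 and 21.8 ± 6.99 CPM at P28 (log2 fold change -1.61 ± 0.41, edgeR adjusted p = 0.0891). Of the 15 tested genes of the nuclear lamina and LINC complex, which ties the nucleus to the cytoskeleton, 1 was called higher and 0 lower, and 3 higher and 2 lower adjusted over the list alone. The called gene was Syne3 (nesprin-3), at 0.198 ± 0.047 CPM at P18 and 11.9 ± 7.18 CPM at P28 (edgeR adjusted p = 0.0434). Its call ended without any of P18 replicates 1 to 4 and P28 replicates 1 and 2 (adjusted p up to 0.160), and with voom and quality weights (0.0942) or no filter (0.0539). Emd (emerin) had a log2 fold change of 1.09 ± 0.26 and Zmpste24, the protease that matures prelamin A, one of -2.45 ± 0.70 (edgeR adjusted p = 0.0773 and 0.121). As with Lmna, the libraries of the ages did not overlap for Lmnb1, Emd and Zmpste24. These were called in 1, 2 and 1 of the 7 alternatives run for single genes other than leaving out a library. Of the 8 fits that left out 1 library, Zmpste24 passed only without P28 replicate 2 (edgeR adjusted p = 0.0269), and Lmnb1 and Emd passed in 0. The list as a whole was not called (camera adjusted p = 0.748, direction down; median log2 fold change -0.31, and -0.39 to -0.11 leaving out 1 library, mean 0.03). The mixed test of fry, for change in either direction, passed (adjusted p = 8.44e-06). It compares a list with no other genes, and 28 of the 36 lists passed it, so this is not particular to lamina genes.

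Genes of the Notch pathway passed no test of a shared direction. Of 32 tested members, 0 were called by edgeR in either direction, over all genes or adjusted over the list alone, with 16 log2 fold changes above 0 and 16 below. An unadjusted p under 0.05 was found for 7; the DESeq2 Wald test called Notch4 higher and Aph1a lower, and voom Aph1a alone. The list had a camera adjusted p of 0.748, with direction up and a median and a mean log2 fold change of -0.05. The mixed test of fry, which asks whether members change in either direction and compares them with no other genes, passed (adjusted p = 0.00109). It passed for 28 of the 36 lists. Notch1 lay at 32.0 ± 11.98 CPM at P18 and 66.6 ± 24.2 CPM at P28 (log2 fold change 1.06 ± 0.38, edgeR adjusted p = 0.221), and Notch4 at 27.1 ± 7.12 and 57.1 ± 14.1 CPM (1.08 ± 0.34, adjusted p = 0.157). Notch2 and Notch3 had log2 fold changes of -0.15 ± 0.43 and 0.05 ± 0.85. Among ligands, those of Jag1, Dll1 and Dll4 were 1.34 ± 0.63, 2.85 ± 1.29 and -1.28 ± 0.68. Aph1a, part of the gamma-secretase that cleaves Notch, had one of -1.20 ± 0.32 and the glycosyltransferase gene Mfng one of 0.80 ± 0.32 (edgeR adjusted p = 0.101 and 0.269). The targets Hes1, Hey1, Heyl and Nrarp had log2 fold changes of 0.31 ± 0.52, -0.15 ± 0.72, -0.17 ± 0.47 and -0.22 ± 0.43. Of 9 tested Notch target genes, 1 was called higher (Cdkn1a), and 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.550). Ccnd1 (cyclin D1) had a log2 fold change of 1.05 ± 0.25, and Myc lay at 176 ± 26.6 CPM at P18 and 87.7 ± 21.6 CPM at P28 (edgeR adjusted p = 0.0773 and 0.0737). Ccnd1 passed without P28 replicate 4 (edgeR adjusted p = 0.0260). Ccnd1 and Myc were each called in 2 of the 7 other alternatives run for single genes. The call of Cdkn1a ended without P18 replicates 2, 3 or 4 or P28 replicates 1 or 3 (adjusted p up to 0.0857).

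**Figure D2:**
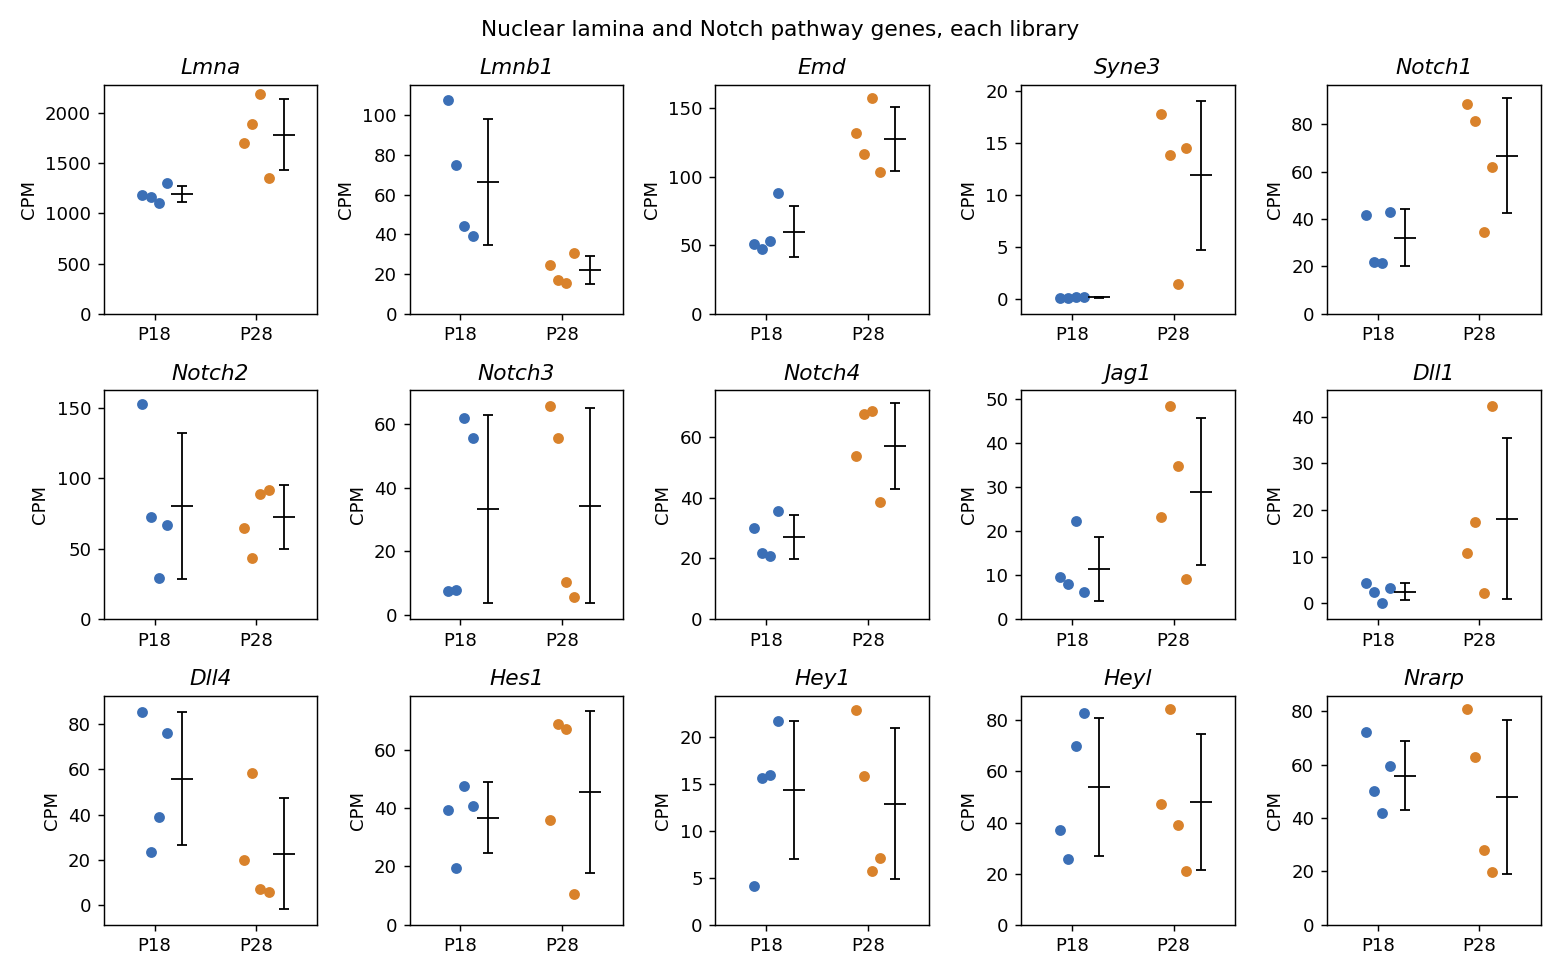
CPM of nuclear lamina and Notch pathway genes in each library (points) with mean and SD (bars, n = 4 per age); axes are linear. Lmna lies between 1108 and 1301 CPM at P18 and between 1351 and 2196 CPM at P28. Notch1, Notch2, Notch3, Jag1, Dll1, Dll4, Hes1, Hey1, Heyl and Nrarp overlap between ages.

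Markers of ligament and tendon fibroblasts went both ways. Of 17 tested ligament and tendon fibroblast genes, 2 were called higher (Fmod and S100a4) and 1 lower (Tnmd), and 3 and 3 adjusted over the list alone (camera adjusted p = 0.584, direction up). S100a4, a calcium-binding protein, rose from 1508 ± 332 to 6445 ± 3611 CPM (log2 fold change 2.10 ± 0.37). It lay at 7481, 2545, 10938 and 4817 CPM in P28 replicates 1 to 4. Like Acp5, it was highest in replicates 1 and 3. Which cells of the captures held it was not tested. Fbln5, an elastic-fibre protein, had a log2 fold change of -2.20 ± 0.48 (edgeR adjusted p = 0.0540). Scx, the tendon transcription factor, lay at 26.4 ± 5.41 and 61.6 ± 75.8 CPM, and Postn (periostin) at 15331 ± 849 and 20855 ± 8041 CPM (log2 fold changes 1.23 ± 0.78 and 0.44 ± 0.24; edgeR adjusted p = 0.516 and 0.433). Without P28 replicate 3 the log2 fold change of Scx was -0.0901. Of 30 tested genes of fibrillar collagens and their processing, 2 were called higher and 1 lower, and 4 and 2 adjusted over the list alone (camera adjusted p = 0.376). Col5a3 rose from 71.5 ± 19.4 to 239 ± 66.6 CPM and Col6a2 from 701 ± 107 to 1382 ± 294 CPM, while P4ha3, a collagen prolyl hydroxylase subunit, fell from 356 ± 63.2 to 104 ± 52.2 CPM. Bmp1, the procollagen C-proteinase, had a log2 fold change of 0.68 ± 0.17 (edgeR adjusted p = 0.0876). Col1a1 lay at 53323 ± 13466 and 72317 ± 9095 CPM and Col3a1 at 35484 ± 5054 and 57209 ± 17188 CPM (log2 fold changes 0.44 ± 0.21 and 0.69 ± 0.22; edgeR adjusted p = 0.358 and 0.171); Col3a1 passed without P28 replicate 2 (edgeR adjusted p = 0.0470) and in the DESeq2 Wald test (0.0390). S100a4, Col5a3, P4ha3 and Col6a2 were called in 3, 4, 2 and 2 of the 8 fits that left out 1 library. Each call ended without P18 replicates 2 or 3 or P28 replicates 1 or 3 (adjusted p up to 0.107, 0.0738, 0.123 and 0.192). That of S100a4 also ended without P18 replicate 4, and those of P4ha3 and Col6a2 also without P18 replicates 1 or 4.

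Matrix-degrading and contractile genes held few calls. Of 21 matrix degradation genes, 1 was called lower and 0 higher, and 2 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.936, direction down; median 0.17 and mean 0.26). The called gene was the metalloproteinase gene Mmp23, from 380 ± 10.8 to 213 ± 32.0 CPM (log2 fold change -0.84 ± 0.18, edgeR adjusted p = 0.0494), whose call held only without P28 replicate 4 among the 8 fits that left out 1 library (otherwise adjusted p up to 0.172) and ended with DESeq2 size factors (0.0539), no filter (0.0535) and 10 counts in 4 libraries (0.0506). Mmp9 had a log2 fold change of 4.40 ± 1.20 and Mmp19 one of -1.18 ± 0.36 (edgeR adjusted p = 0.107 and 0.145). Of 13 actomyosin and smooth muscle genes, 1 was called lower and 0 higher, and 3 lower adjusted over the list alone (camera adjusted p = 0.205). Tropomyosin gene Tpm1 fell from 1383 ± 143 to 632 ± 70.7 CPM (log2 fold change -1.13 ± 0.17, edgeR adjusted p = 0.0153). Its call ended without P18 replicates 2 or 3 or P28 replicate 1 (adjusted p up to 0.0743). Acta2 and Tagln had log2 fold changes of -2.07 ± 0.56 and -0.60 ± 0.20, and Srf, a transcription factor of contractile genes, one of 1.39 ± 0.51 (edgeR adjusted p = 0.105, 0.175 and 0.223; Srf 0.90 without P28 replicate 3).

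Of the 36 gene lists, 8 were called by camera. Osteoclast, epithelial, ribosomal protein and stress genes lay higher at P28, and cell cycle, neutrophil, erythroid and enamel organ genes lower. None of these 8 calls held with an estimated correlation (0 of 36 lists, 1 at an unadjusted p under 0.05; fry called 4 for a shared direction and 28 for change in either direction), and 4 of the 35 ways to split the libraries into 4 and 4, the split by age included, gave 8 or more called lists.

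**Figure D3:**
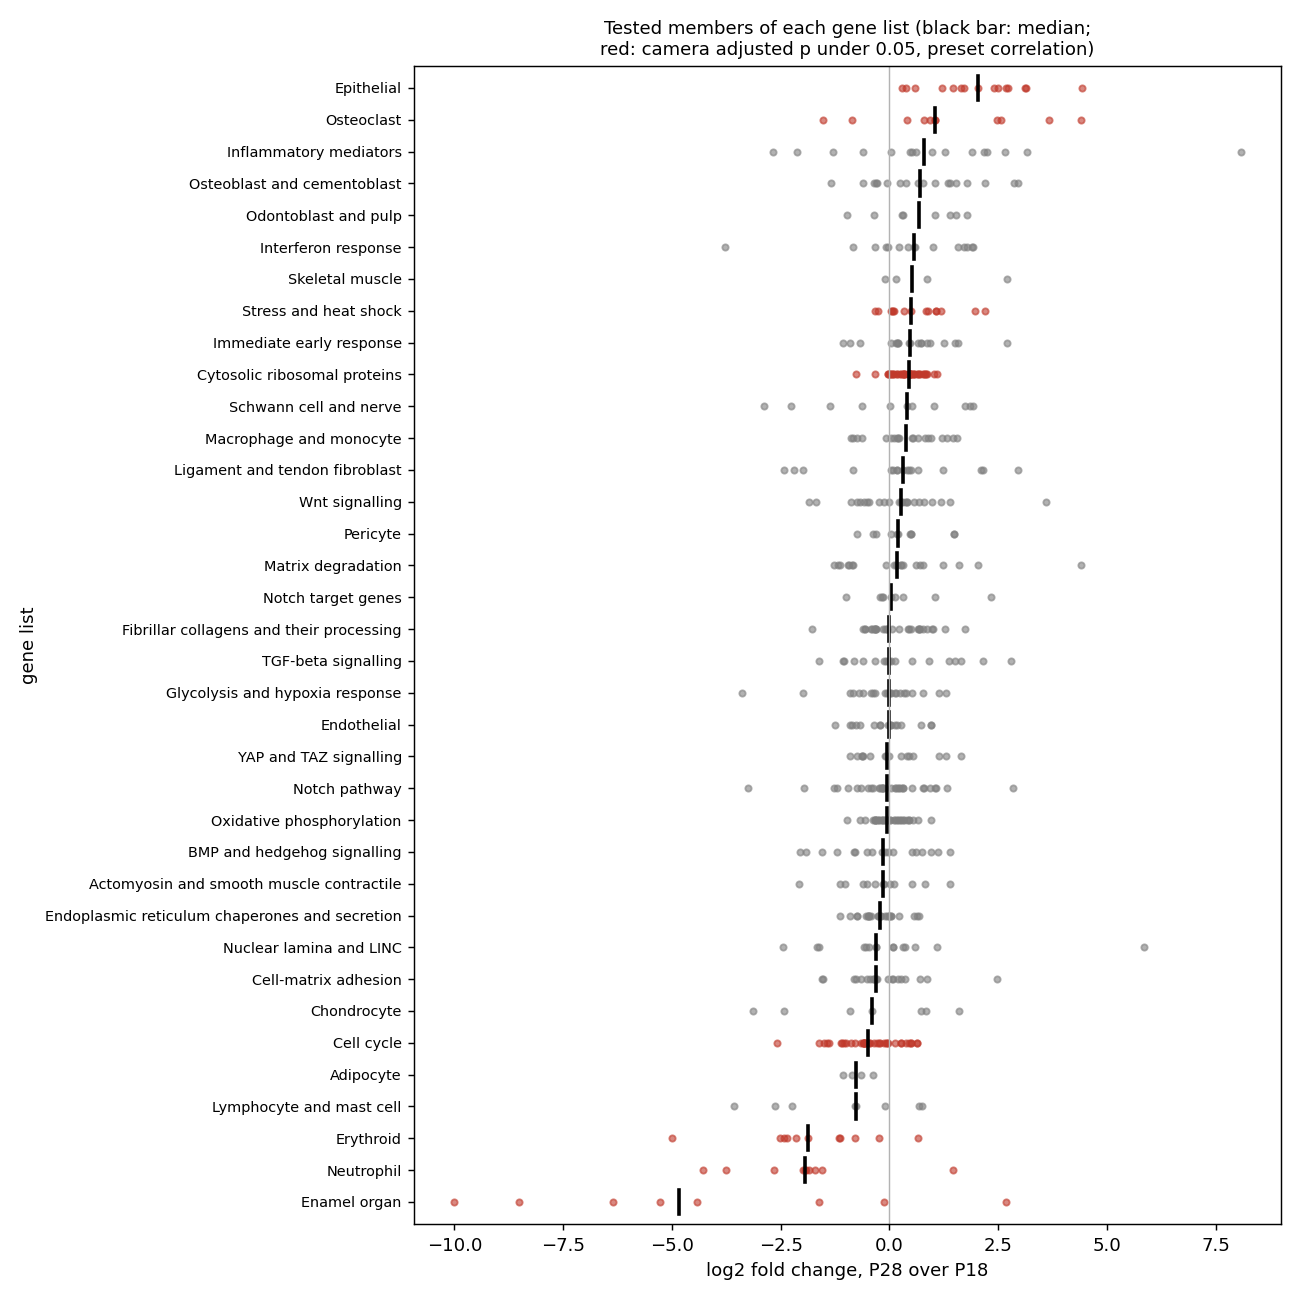
Log2 fold change (P28 over P18) of each tested member (points) of the 36 gene lists, with the median as a black bar; red lists passed camera with the preset correlation. The enamel organ list has the lowest median (-4.85). The epithelial list has the highest (2.03) with all 8 libraries. Without P28 replicate 2 it has 0.88, below the inflammatory mediator (1.17), osteoclast (1.10) and skeletal muscle (0.99) lists.

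Bone-resorbing cell genes lay higher in P28 replicates 1 and 3. Their mean log2 CPM over the list was 6.45 and 7.04 there. P28 replicates 2 and 4 (4.93 and 5.12) lay within the range of the P18 libraries (3.88 to 5.17). Of 11 tested osteoclast genes 9 had a log2 fold change above 0, 1 was called higher (Acp5) and 0 lower, and 3 higher adjusted over the list alone (camera adjusted p = 0.0110; adjusted p = 0.620 with an estimated correlation). Acp5 went from 90.1 ± 33.9 to 1142 ± 1184 CPM, with 1555 and 2632 CPM in P28 replicates 1 and 3 and 147 and 235 CPM in replicates 2 and 4. Its call (edgeR adjusted p = 0.0494) held only without P28 replicate 2 or 4 among the 8 fits that left out 1 library (otherwise up to 0.173) and ended with upper-quartile scaling (0.0517) and 10 counts in 4 libraries (0.0506). Mmp9, the gelatinase of osteoclasts and neutrophils, lay at 333 and 449 CPM in P28 replicates 1 and 3 and at 14.8 and 18.7 CPM in replicates 2 and 4. Tcirg1, a proton pump subunit, and Nfatc1 had log2 fold changes of 1.05 ± 0.34 and 0.79 ± 0.31 (edgeR adjusted p = 0.169 and 0.250). The list's call ended without P18 replicate 1 (camera adjusted p = 0.0518) or P28 replicate 3 (0.0654). Of 18 tested osteoblast and cementoblast genes, 1 was called higher (Bglap), and 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.106, direction up; 0.00700 without P28 replicate 3). Ibsp and Spp1, which encode bone sialoprotein and osteopontin, had log2 fold changes of 1.34 ± 0.29 and 2.95 ± 0.65, and Enpp1, which makes the mineralization inhibitor pyrophosphate, one of -1.33 ± 0.43 (edgeR adjusted p = 0.0523, 0.0579 and 0.168). Ibsp and Spp1 were each called in 1 of the 8 fits that left out 1 library (edgeR adjusted p = 0.0484 and 0.0251). Each was also called in 3 of the 7 other alternatives run for single genes. The call of Bglap ended without P18 replicates 2, 3 or 4 or P28 replicate 1 (edgeR adjusted p up to 0.0979).

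Enamel organ genes lay lower at P28. Of 8 tested, 7 had log2 fold changes below 0, 2 were called lower (Amtn and Ambn) and 0 higher, and 5 lower adjusted over the list alone, with a median log2 fold change of -4.85 (camera adjusted p = 0.0126; adjusted p = 0.620 with an estimated correlation; 0.0718 without P18 replicate 1). Ambn lay at 2329, 171, 692 and 9.72 CPM in P18 replicates 1 to 4 and at no more than 4.58 CPM in any P28 library; its call ended without P28 replicate 1 or 3 (edgeR adjusted p up to 0.0917), and that of Amtn without P18 replicate 2 or P28 replicates 1 or 3 (up to 0.0873). Amelx, which encodes the main enamel protein amelogenin, went from 159 ± 189 to 1.75 ± 2.32 CPM and Calb1 from 36.0 ± 39.1 to 0.892 ± 0.722 CPM (edgeR adjusted p = 0.0958 and 0.124). By mean log2 CPM of the list, P18 replicate 4 (0.772) lay within the range of the P28 libraries (0.0105 to 2.37). Epithelial genes lay the other way. All 15 tested had log2 fold changes above 0, with 0 called by edgeR over all genes or adjusted over the list alone (6 at an unadjusted p under 0.05; 1, Itgb4, called by DESeq2 and 0 by voom; camera adjusted p = 0.00824; adjusted p = 0.620 with an estimated correlation). The basal keratin genes Krt5 and Krt17 reached 1049 and 1805 CPM in P28 replicate 2. Krt17 did not pass 44.1 CPM in any other library, and without P28 replicate 2 its log2 fold change was -1.11 and the list's call ended (camera adjusted p = 0.144). Itgb4, an integrin subunit of hemidesmosomes, and Pkp1, of desmosomes, had log2 fold changes of 1.65 ± 0.51 and 2.68 ± 1.09 (edgeR adjusted p = 0.147 and 0.278). That of Pkp1 was 0.26 without P28 replicate 2, which held 270 CPM against at most 27.2 in any other library.

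Blood and marrow cell genes and cell cycle genes lay lower at P28. Of 11 erythroid genes 10 had log2 fold changes below 0, 1 was called lower, and 4 lower adjusted over the list alone (camera adjusted p = 0.000437; adjusted p = 0.620 with an estimated correlation). The called gene was Klf1, an erythroid transcription factor, from 14.7 ± 10.5 to 0.440 ± 0.292 CPM (edgeR adjusted p = 0.0471), a call that held only without P28 replicate 4 among the 8 fits that left out 1 library (otherwise up to 0.220) and ended with no filter (0.0559) and with voom and quality weights (0.0755). Alas2, Ahsp and Slc4a1, of heme synthesis, haemoglobin folding and the red cell membrane, had log2 fold changes of -2.52 ± 0.65, -2.43 ± 0.66 and -2.14 ± 0.70 (edgeR adjusted p = 0.0928, 0.107 and 0.171). By mean log2 CPM of the neutrophil list, P18 replicate 3 (1.499) lay within the range of the P28 libraries (-0.21 to 3.40) and the other P18 libraries above it. Of 10 neutrophil genes 9 had log2 fold changes below 0, with 0 called by edgeR over all genes (3 at an unadjusted p under 0.05; 2, Fcnb and Ngp, called lower by DESeq2 and 0 by voom) and 2 lower adjusted over the list alone (camera adjusted p = 0.00665; adjusted p = 0.620 with an estimated correlation). The granule genes Fcnb, Ngp and Np4 and the calprotectin gene S100a8 had log2 fold changes of -3.75 ± 0.80, -4.29 ± 1.03, -1.95 ± 0.92 and -1.98 ± 0.76 (edgeR adjusted p = 0.0521, 0.0773, 0.359 and 0.246; Np4 -1.08 without P18 replicate 2). Of 38 cell cycle genes 29 had log2 fold changes below 0, with a median of -0.49 and 0 called by edgeR over all genes or adjusted over the list alone (9 at an unadjusted p under 0.05; 2, Ccna2 and Racgap1, called lower by DESeq2 and 0 by voom; camera adjusted p = 0.0110; adjusted p = 0.620 with an estimated correlation). Ccna2 (cyclin A2), Racgap1, Bub1 and Mcm2 had log2 fold changes of -1.61 ± 0.43, -2.58 ± 0.84, -1.42 ± 0.49 and -1.50 ± 0.51 (edgeR adjusted p = 0.103, 0.171, 0.189 and 0.191). The cell cycle call ended without P18 replicate 2 (camera adjusted p = 0.0606) or P28 replicate 2 (0.119).

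Ribosomal protein and stress genes were called higher at P28 as lists. The mean log2 CPM of ribosomal protein genes was 6.46 to 6.68 in P28 replicates 1 to 3, above the P18 libraries (5.85 to 6.32), but 5.74 in P28 replicate 4, below all of them. Of 40 cytosolic ribosomal protein genes 35 had log2 fold changes above 0, with a median of 0.45 (0.28 without P28 replicate 3) and 0 called by edgeR over all genes or adjusted over the list alone (10 at an unadjusted p under 0.05; 1 called higher by DESeq2 and 1 by voom; camera adjusted p = 0.00143; adjusted p = 0.721 with an estimated correlation). Rpl13 and Rps24 had log2 fold changes of 0.81 ± 0.28 and 0.77 ± 0.27 (edgeR adjusted p = 0.192 and 0.213). Without P28 replicate 4, 3 of the 40 were called higher, Rpl13 and Rps24 among them (edgeR adjusted p = 0.0483 and 0.0414). Of 15 stress and heat shock genes 13 had log2 fold changes above 0, 1 was called higher, and 2 higher adjusted over the list alone (camera adjusted p = 0.0110; adjusted p = 0.570 with an estimated correlation; 0.0584 without P28 replicate 4). The called gene was the small heat shock protein gene Hspb1, from 47.3 ± 13.3 to 217 ± 137 CPM (edgeR adjusted p = 0.0401), whose call held only without P28 replicate 4 among the 8 fits that left out 1 library (otherwise up to 0.137). Gadd45g, Bag3 and Hspb8 had log2 fold changes of 0.85 ± 0.20, 0.89 ± 0.30 and 1.06 ± 0.41 (edgeR adjusted p = 0.0753, 0.179 and 0.253).

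**Figure D4:**
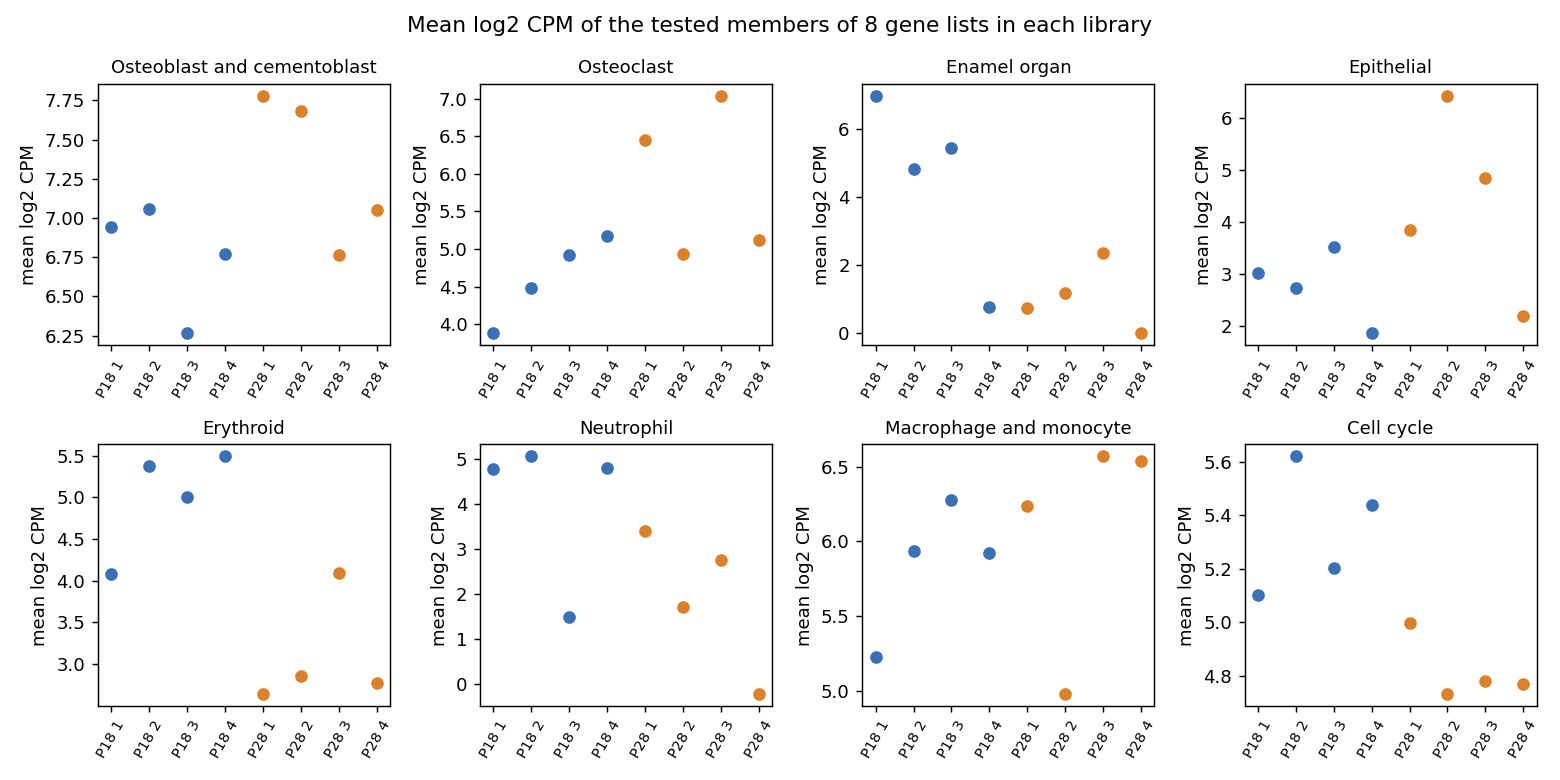
Mean log2 CPM of the tested members of 8 gene lists in each library (blue, P18; orange, P28; 1 point per library). The osteoclast mean is highest in P28 replicates 1 and 3 (6.45 and 7.04), the epithelial mean in P28 replicate 2 (6.44) and the enamel organ mean in P18 replicate 1 (6.99).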

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

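The tests of depth and profile for P28 replicate 4 were set out before their results were seen. In 228 groups of 4 libraries (named genes, described lists and library measures), 10 held a library far from the other 3 by a gap test that chance passes in about 1 of 20 groups, which is 11.4 of the 228.

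P28 replicate 4 lay at 163 on the first principal component, against -21.5 to 3.60 for the other P28 libraries, and leaving it out raised the calls from 98 to 215. Low depth as the cause was argued against: with all libraries thinned to its total of 5252693 counts, the other 7 called a median of 241 genes (221 to 262 in 10 draws) and all 8 called 93 to 111. Its profile stayed apart at equal total counts, with a median correlation of 0.769 with the other P28 libraries against a lowest value of 0.816 among these. A different tissue content of that capture, its RNA quality, a lower library complexity (10063 genes with a count before thinning, against 11298 to 11661 in the other P28 libraries) and a true difference between animals may each account for this and stay open; none was tested.

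Of the single genes, Amtn in P28 replicate 3 lay at 0.163 CPM with the other P28 libraries at 0, and Ahsp there at 40.0 CPM against 8.11 to 9.57. Syne3 and Mcm2 in the same library lay at 1.47 CPM against 13.9 to 17.8 and at 6.03 CPM against 35.4 to 48.7. Mcm10 in P18 replicate 4 lay at 2.14 CPM against 17.0 to 24.0, and Col6a2 in that library at 861 CPM against 642 to 657. Dll1 had a count of 0 in P18 replicate 3, against 2.49 to 4.34 CPM in the other P18 libraries. The mean log2 CPM of the neutrophil list was 1.499 in P18 replicate 3 against 4.77 to 5.05, and that of the erythroid list 4.10 in P28 replicate 3 against 2.64 to 2.86.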

How the results depend on the processing

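The mixed test of fry was chosen only after the results were seen; the other alternatives were planned. The 54 higher and 44 lower genes became 404 and 326 in the DESeq2 Wald test (which kept all 98), 175 and 132 with voom and quality weights, 86 and 83 on the authors' normalized values, and 8 and 8 in glmTreat against a fold of 1.5, where the higher bar itself lowers the count; for the others the cause was not tested. Other scalings and filters gave 50 to 66 higher and 42 to 49 lower, and leaving out 1 library 4 to 110 higher and 5 to 105 lower. Subject numbers repeat across ages, but 0 of 8 libraries correlated best with their own number (same-number correlations -0.0196 to 0.0019). The numbers thus gave no sign of pairing. With 4 libraries per age this check cannot exclude a shared effect of litter or batch. With the replicate block 16 and 10 genes were called, 23 of them among the 98. Single genes were not run in glmTreat or on the authors' normalized values. Lmna kept its direction in the 7 alternatives run for it (adjusted p 0.0198 to 0.274, leaving out 1 library 0.0481 to 0.357): its log2 fold change was 0.59 and past the threshold in the DESeq2 Wald test, and 0.47 to 0.70 leaving out 1 library. The 8 called lists became 0 with an estimated correlation. That estimate was 0.265 to 0.716 for the osteoclast, erythroid, enamel organ, epithelial, ribosomal protein and neutrophil lists, far above the preset of 0.01. It was 0.0437 for the cell cycle list and -0.029 for the stress list, whose calls ended too. Fry compares no list with other genes. It called 4 lists for a shared direction (erythroid, adipocyte, chondrocyte and stress) and 28 for change in either direction. By camera with the preset correlation, the called lists stayed 8 under other scaling, filter and block, and 6 to 10 leaving out 1 library. The Notch pathway list had adjusted p of 0.647 to 0.913 in the other settings that test a shared direction, 0.533 to 0.963 leaving out 1 library, and 0.00109 in the mixed test of fry.

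Of the 33 called among 93 named genes, none reversed, and 23 were called in the other scalings, tests (DESeq2 and voom) and filters. The calls kept were 6 in all 8 left-out fits, 31 without P28 replicate 4 and 15 with the replicate block. Without P18 replicate 2, 3 of the 12 higher and 4 of the 12 lower genes of the rule stayed called. Among genes not called, Notch2 reversed with voom and quality weights (0.0695) and the block (0.0073), and Nrarp with voom (0.0080), all near 0. Leaving out 1 library reversed, in at least 1 fit, Notch2 (-0.44 to 0.36), Notch3 (-0.48 to 0.53), Hey1 (-0.58 to 0.12), Heyl (-0.58 to 0.12), Nrarp (-0.60 to 0.0342), Scx (-0.0901 to 1.62) and Krt17 (-1.11 to 5.03). The self-test recovered 10.2% of simulated 2-fold changes, all in genes above a minimum mean CPM. A gene that was not called is thus not shown to be unchanged. By edgeR the age split called 98 genes (1523 at an unadjusted p under 0.05) and no other of the 35 splits of the 8 libraries called any (highest 0; 149 to 1138 unadjusted), 1 split of 35, which excludes chance at the 0.05 level. For lists, 4 of 35 splits gave as many as the 8 called (highest other 10), so chance is not excluded for their number; the 2 highest put P28 replicate 4 with 3 P18 libraries. By the mixed test 1 of 35 splits, that by age, called as many as 28 lists (highest other 5). That test compares lists with no other genes and was chosen after the results were seen. Its count of lists thus restates the change of single genes and adds no support for any list.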

Other observations

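The 3 tests on enamel genes, the test of the macrophage lineage and the test of melanocyte genes were chosen only after the results were seen; those of bone and of imprinted genes were set out before. Of the 20 lists not described in the results, 0 were called by camera (4 at an unadjusted p under 0.05). With an estimated correlation 0 were called, and by fry 2. In 4 of these lists 5 genes were called singly. Klf4 (of 19 immediate early response genes, camera adjusted p = 0.106) and Rsad2 (lower, of 15 interferon response genes, 0.697) were also named by the fixed rule. The other genes are named here after their values were seen. Hapln1, a cartilage link protein, had a log2 fold change of -2.42 ± 0.37 (of 7 chondrocyte genes, camera adjusted p = 0.205). Cox7b and Sdha, of the respiratory chain, had log2 fold changes of 0.97 ± 0.20 and -0.97 ± 0.18 (of 34 oxidative phosphorylation genes, 0.918). The call of Rsad2 held only without P28 replicate 3 among the 8 fits that left out 1 library (otherwise edgeR adjusted p up to 0.140). The call of Hapln1 ended without P18 replicates 2 or 4 or P28 replicate 1 (edgeR adjusted p up to 0.0610), that of Sdha without any library other than P28 replicates 2 or 4 (up to 0.128), and that of Cox7b without any other than P28 replicate 4 (up to 0.173) and with upper-quartile scaling (0.0541). The remaining 16 lists held 0 edgeR calls over all genes (56 of 247 distinct genes at an unadjusted p under 0.05; 25 called by DESeq2 and 13 by voom). Adjusted over the list alone, the calls higher and lower were 1 and 4 of 25 endoplasmic reticulum chaperone and secretion genes (camera adjusted p = 0.106), 3 and 0 of 19 TGF-beta genes (0.376), 3 and 0 of 18 endothelial genes (0.936), 2 and 1 of 21 cell-matrix adhesion genes (0.550), 2 and 1 of 16 inflammatory mediators (0.172), 1 and 1 of 8 odontoblast and pulp genes (0.141), and 1 and 0 of 16 YAP and TAZ (0.835), 25 Wnt (0.762) and 11 pericyte genes (0.214). They were 0 of 18 BMP and hedgehog (0.918), 23 glycolysis and hypoxia (0.749), 20 macrophage (0.214), 8 lymphocyte and mast cell (0.106), 11 Schwann cell (0.789), 4 skeletal muscle (0.550) and 4 adipocyte genes (0.119). The test pointed up while the median lay below 0 for the BMP, oxidative phosphorylation, YAP, TGF-beta and endothelial lists; the mean lay above 0 for the YAP and TGF-beta lists (0.10 and 0.28).

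Leaving out 1 library made some of these calls: the endoplasmic reticulum list without P28 replicate 4 (lower, camera adjusted p = 0.00257), the macrophage list without P28 replicate 2 (higher, 0.00371), the immediate early list without P18 replicate 4 or P28 replicates 1 or 4 (higher, 0.0201 to 0.0288), and the lymphocyte list without P18 replicates 2 or 4 or P28 replicates 1 or 4 (lower, 0.00257 to 0.0153).

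The fall of enamel organ genes at P28 was weighed against 3 explanations. A lower share of all epithelium would lower epithelial genes too, but their median log2 fold change was 2.03 (0.88 without P28 replicate 2). This argues against a fall of all epithelium together. The 2 lists may stem from different epithelia, which was not tested. The enamel list minus the epithelial list changed by -4.98 in mean log2 CPM (exact permutation p = 0.0286, the smallest possible). Both directions were known when that test was chosen, so its p adds no support. P18 replicate 1 alone stays open for the list: without it the median log2 fold change was -3.48 (SD over the 8 genes 3.92) and the list's call ended (camera adjusted p = 0.0718), while Ambn and Amtn were still called (edgeR adjusted p = 0.0412 and 0.0476). The 8 enamel genes deviated together from their age means, with a median pairwise correlation of 0.365 over the 8 libraries, above 98.3% of 1000 random lists matched on mean expression. This is consistent with captures that may differ in how much enamel organ they include; a true change of these cells with age was not separated from it.

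The higher level of osteoclast genes stayed open against both explanations tested. Bone entering some captures could raise osteoclast and osteoblast genes in the same animals, but the list means had a correlation of -0.396 after removing age means (576 exact permutations within age, p = 0.396; Spearman rho -0.286, exact p = 0.472; r = 0.143 without P28 replicates 2 and 3, whose osteoclast scores lay farthest from the median once age means were removed). A rise of the whole macrophage lineage could move both lists alike; the osteoclast list minus the macrophage list changed by 1.03 in mean log2 CPM (exact permutation p = 0.114). With 4 animals per age these cannot be told apart from a change of the ligament's own osteoclasts with age, which is untested.

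Mest fell, as did H19, another imprinted gene, from 111 ± 30.1 to 24.6 ± 4.55 CPM (edgeR adjusted p = 0.00681, called in all 8 fits that left out 1 library). Nnat, also imprinted, went against them and rose from 27.9 ± 10.7 to 126 ± 49.7 CPM (edgeR adjusted p = 0.0264; not called without any of P18 replicates 1 to 4 or P28 replicates 1 or 3, up to 0.0921); both were named after their values were seen. The hypothesis that other imprinted genes fell too was tested on a list of 18 that leaves out these 3, written after the data were examined but before its members' values were seen (15 in the table, 13 tested). Of these, 10 had log2 fold changes below 0, with a median of -0.67, also with Zim1, at 0 in P28, set to its bound; 0 were called by edgeR over all genes (3 at an unadjusted p under 0.05; 3 called by DESeq2 and 0 by voom) and 3 lower adjusted over the list alone (Peg3, Grb10 and Zim1). The list lay lower (camera p = 0.0109; p = 0.0551 with an estimated correlation), which may reflect a wider fall of part of these genes, though not of all: besides Nnat, Igf2 and Igf2r had log2 fold changes of 0.73 ± 0.39 and 0.78 ± 0.42 (edgeR adjusted p = 0.427 and 0.425).

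Melanocytes in the P28 captures might be thought to bring the Mlana counts. Of a melanocyte list, Pmel and Dct were not analysed here. Tyrp1 and Tyr had a count of 0 in all 4 P28 libraries, against 3842 counts of Mlana. At the limit of 3 counts, Tyrp1 stood at 0.0781% of Mlana. The counts of Tyrp1 and Tyr argue against melanocytes, but other listed genes were divided. Of the other listed genes in the table, Slc45a2 had 0 counts at P28, Mlph 33, Gpr143 11, Sox10 126 and Mitf 503. Sox10 and Mitf are also active in other cells. Mlph and Gpr143 had a mean of 0 CPM at P18 and of 0.507 and 0.287 CPM at P28. These low levels, seen at P28 alone, lie near the P28 limit for a count of 0 (a mean of 0.340 CPM). They are only weak support for melanocytes, which are not excluded. The mean of Sox10 was 2.60 CPM at P18 and 2.61 CPM at P28, and that of Mitf was higher at P28.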
